A study of Mus musculus with 12 samples.

How the data were processed

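RNA of SMARTA CD4 T cells was measured on 12 Affymetrix arrays, 1 per sample, in 4 groups of 3: Tcf7-deficient (KO) and wild-type (WT) TFH cells, and KO and WT Th1 cells, all taken on day 8 after infection. The deposited values are on the log2 scale: per the labels, the authors used Affymetrix Expression Console with RMA, which corrects background, quantile-normalizes the arrays and gives 1 value per probe set. The versions of these programs are not given in the sources used here. The labelling text names a human array, while the organism and the probe annotation are mouse, so the platform annotation was used for gene names. Values ran from 2.39 to 13.6 and array medians from 6.44 to 6.55. The precision of each group mean is limited by its 3 arrays. The labels do not say that replicates came from separate animals, so each p-value measures only the spread between these samples. Sex-linked genes set the arrays numbered 2 apart from the others, so those are not technical repeats of arrays 1 and 3. For arrays 1 and 3 this stays open.

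Of 41345 probe sets, 23521 were annotated with 1 gene, 1814 with several and 16010 with none. The brightest probe set stood for each of 22180 genes, of which 1082 had several probe sets. Tcf7 was not analysed here, since no probe set was annotated with Tcf7 alone, so its level could not serve as a check of the genotype labels. The annotation gives no genome build, so no positions are printed.

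Group means were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no intensity trend) over all 12 arrays, with 8 residual and 6.52 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 22180 genes of each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were KO minus WT in TFH cells, KO minus WT in Th1 cells, TFH minus Th1 in WT cells, TFH minus Th1 in KO cells, and the interaction, which is the genotype effect in TFH cells minus that in Th1 cells. Errors beside group means are standard deviations (SD) and errors beside log2 differences are limma standard errors (SE).

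The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the additions stated as such. The 22 gene lists were TFH program, Th1 program, cytotoxic effector genes, memory and quiescence genes, canonical Wnt targets, Th2, Th17 and Treg genes, cell cycle genes, type I interferon response, chemokine and homing receptors, co-stimulatory and co-inhibitory receptors, cytokine receptors and STAT pathway, TCR-induced early genes, glycolysis and HIF targets, apoptosis regulators, sex-linked genes, and markers of B cells, plasma cells, myeloid and dendritic cells, CD8 T and NK cells and erythroid cells. They name 338 genes, of which 300 were measured. Some genes stand in several lists. The 21 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 105 tests (21 lists in 5 comparisons). Camera with an estimated correlation and the rotation test fry were alternatives.

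Named genes were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (for the interaction, among called genes), without predicted genes, small RNAs, olfactory receptors, receptor segments and sex-linked genes. To these were added up to 4 called members of each list and 14 fixed genes. Genes named outside this rule are stated as chosen after their values were seen.

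Replicate numbers were checked as possible pairs. After each group mean was removed, samples of the same number correlated best, at r of at least 0.1 in each of 3 pairs, between KO and WT Th1 cells (0.26, 0.18 and 0.30) and between WT TFH and WT Th1 cells (0.43, 0.42 and 0.32). KO and WT TFH cells gave 0.07, -0.01 and 0.21, and KO TFH and KO Th1 cells gave 0.03, 0.18 and 0.32. KO TFH and KO Th1 arrays of the same number were the best matches too, but number 1 lay under 0.1. Since not all comparisons reached this mark, the number was left out of the model and used as a block in an alternative.

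The alternatives were the mean of a gene's probe sets, every probe set, dim genes left out, repeated quantile normalization, median centring, cyclic loess, an intensity trend with robust eBayes, array weights, the replicate number as a fixed or random block, a fit to the compared groups only, and each of the 12 arrays left out in turn. A sex term, KO TFH arrays 1 and 3 left out, and all 4 arrays numbered 2 left out were added after seeing the data, as were the genotype effects of single arrays by number and the overlap with different WT TFH arrays in each comparison. Other splits of the arrays into the same group sizes were fitted alike. The method was tested on simulated data with 200 changed genes: at a log2 change of 1, between 92.5% and 98.5% were recovered in the group comparisons and 83.6% in the interaction. At a log2 change of 0.5, the interaction recovered 29.9%. False calls numbered 5 to 13 of 22180 genes, with 200 genes changed. The simulated noise was normal, independent between arrays and, for each gene, of equal spread on all 12. The real arrays differ in range and share some spread by number, so these counts do not give the error rate of the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.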

Results

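Gene expression was measured in SMARTA cells, transgenic CD4 T cells that recognise an epitope of lymphocytic choriomeningitis virus (LCMV), on day 8 of the infection. FACS parted them into T follicular helper (TFH) cells, which help B cells make antibody, and Th1 cells, which make interferon gamma and act against infected cells. The cells were WT or lacked Tcf7, the gene of the transcription factor TCF1 (KO). Each of the 4 groups had 3 arrays. Correlations between arrays lay between 0.977 and 0.993 over all probe sets, and over the tested genes the first principal component held 41.4% of the variance. On it, KO TFH arrays 1 and 2 stood at -23.7 and -20.4 and KO TFH array 3 at -8.93, nearer to the Th1 arrays (14.5 to 23.4). KO TFH arrays 1 and 3 had interquartile ranges of 2.82 log2 units, against 2.94 to 3.10 on the other arrays.

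The first comparison asked what TCF1 deficiency changes in TFH cells. Cxcr5 and Bcl6, which mark the subset, had like means in both genotypes: Cxcr5, the chemokine receptor that leads T cells into B cell follicles (probe set 17526310), was 11.39 ± 0.07 (SD, n = 3) in WT and 11.33 ± 0.27 (SD, n = 3) in KO cells, and Bcl6, the transcription factor that directs TFH differentiation (17329433), was 9.52 ± 0.35 and 9.62 ± 0.44 (SD, n = 3). No change was detected for either (log2 difference -0.06, adjusted p = 0.82, and 0.10, adjusted p = 0.797, limma). The cells of both genotypes were sorted as TFH cells first, so levels tied to the sort can be alike through it. In contrast, some genes typical of Th1 cells were higher in KO TFH cells, 9 of the 23 in the Th1 program. Cxcr6, a chemokine receptor of effector T cells (17523642), rose from 9.19 ± 0.17 to 11.45 ± 0.23, and Il2ra, the high-affinity chain of the IL-2 receptor, from 6.63 ± 0.30 to 8.47 ± 0.09 (SD, n = 3). Prdm1, which encodes Blimp1, a repressor of the TFH fate (17240645), rose from 7.0 ± 0.16 to 8.25 ± 0.25, while Id3, an inhibitor of E proteins (17420016), fell from 8.96 ± 0.27 to 8.00 ± 0.33 (SD, n = 3). Ctse, the protease cathepsin E (17217035), fell from 12.88 ± 0.06 to 10.38 ± 0.50 (SD, n = 3).

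With limma and Benjamini-Hochberg adjustment, 1054 of 22180 genes were called between KO and WT TFH cells, 293 higher and 761 lower in KO, and 101 of them differed at least 2-fold (57 higher, 44 lower). At an unadjusted p under 0.05 there were 5258. The groups of 1046 called genes did not overlap, and over all genes 24.6% of genes had no overlap, where chance gives 10%. After Ctse, at a log2 difference of -2.49 (SE 0.18, adjusted p = 2.01e-06), the largest falls were Esm1, a secreted proteoglycan, at -2.0, Nsg2, a vesicle protein, at -1.96, Ccdc141 at -1.95 and Mapk11, a p38 kinase, at -1.81. Ccdc126 at -1.54, Cpm, a carboxypeptidase, at -1.52, Elovl6, a fatty acid elongase, at -1.52, Tmprss11e, a serine protease, at -1.49, and Cd8b1, the CD8 beta chain, at -1.47 followed. The adjusted p of these 9 genes ran from 8.15e-05 to 0.00142. The largest rises were Ccr8, a chemokine receptor of Th2 and regulatory cells (17523158), at 2.43 (SE 0.20, adjusted p = 1.05e-05), Gzmb, the killing protease granzyme B (17307033), at 2.29 (SE 0.46, adjusted p = 0.0131), and Cxcr6 at 2.25 (SE 0.12, adjusted p = 9.89e-08). Mest, an imprinted gene, was at 2.19, Lamc1, a laminin chain, at 2.08, Rgs1, a brake on chemokine receptor signalling, at 2.05, and Dnase1l3, a secreted DNase, at 2.02. Dennd5a, a trafficking regulator, was at 1.99, Susd2, a membrane protein, at 1.89, and Il2ra at 1.84. Their adjusted p ran from 7.94e-08 for Lamc1 to 0.0131 for Gzmb. Gzmb was 7.80, 8.87 and 10.54 on the KO TFH arrays, against a WT mean of 6.78 ± 0.54 (SD, n = 3), and its call was lost with an intensity trend and robust variances (adjusted p = 0.0648, the highest over its alternatives). Without KO TFH arrays 1 and 3, Ccdc126 was at -0.96, and Elovl6 at -1.01 and Dnase1l3 lost their calls (adjusted p = 0.109 and 0.0945).

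The higher and lower shares depended on the scaling, and the count depended on single arrays. Of the calls, 27.8% were higher in KO, against 38.0% of 718 after repeated quantile normalization, 39.4% of 709 after cyclic loess and 15.2% of 1395 after median centring. The count was 267 without WT TFH array 1, 650 without WT TFH array 2, 425 without WT TFH array 3, 465 without KO TFH array 1, 3264 without KO TFH array 2 and 331 without KO TFH array 3. With KO TFH arrays 1 and 3 left out it was 131, with 1 KO TFH array remaining, assumed to vary like the other groups.

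Among the gene lists, the Th1 program had the largest mean difference between KO and WT TFH cells, with Th2 genes close behind at 0.61, and the lowest adjusted p in camera with the preset correlation. Fry and the estimated correlation gave lower adjusted p for Th2 and Treg genes. In the Th1 program, 9 of 23 measured members rose, none fell and 14 did not pass (mean log2 difference 0.63, camera adjusted p = 2.14e-11, but adjusted p = 0.132 with an estimated correlation), and 14 rose and 2 fell when adjusted over the list alone. Examples are Cxcr6, Il2ra, Ccl5, a chemokine of effector cells, at 1.67, and Prdm1 at 1.25 (adjusted p = 4.93e-05). Tbx21, which encodes the Th1 regulator T-bet, was at 0.20 (adjusted p = 0.429) and Ifng, interferon gamma, at 0.52 (adjusted p = 0.063). Among cytotoxic effector genes, 5 of 18 rose and 1 fell (camera adjusted p = 0.00397, and adjusted p = 0.681 with an estimated correlation), with 7 and 2 when adjusted over the list alone. Risers were Gzmb, Fasl, the death ligand, at 1.21, Cx3cr1, a receptor of effector cells, at 1.17, and Prf1, perforin, at 1.09. The 1 that fell was Crtam, named after its values were seen, at -1.08. On KO TFH array 3, the 42 abundant Th1 genes stood at a median of 41.1% of the way from the WT TFH to the KO Th1 level, against 7.73% on arrays 1 and 2. These genes were called higher in WT Th1 than in WT TFH cells. Their KO Th1 level was at least 9 and at least 2 log2 units above the WT TFH level. The cytotoxic list was not past the threshold without KO TFH array 3 (adjusted p = 0.099), with the members shared with other lists left out (0.131) or with fry (0.277), and Prf1 was 0.71 without that array and lost its call without WT TFH array 3 (adjusted p = 0.0596). With KO TFH arrays 1 and 3 left out the call of Fasl was lost (adjusted p = 0.109).

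**Figure D1:**
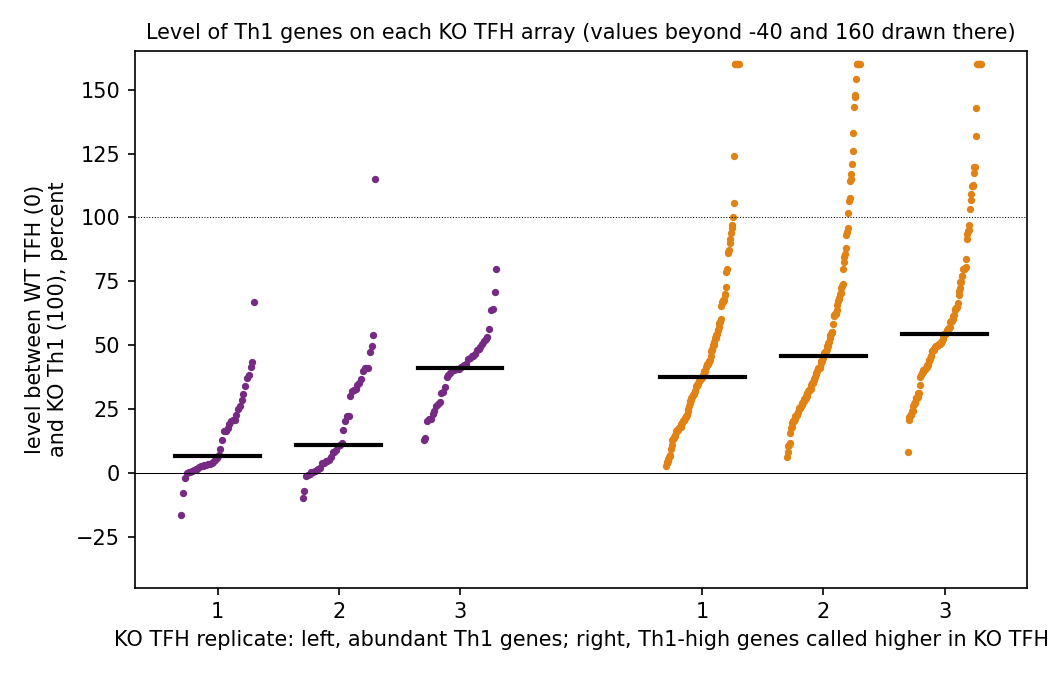
Share of the way from the WT TFH level (0) to the KO Th1 level (100) on the linear scale (y axis, percent) for each KO TFH array (x axis); each point is 1 gene, left the 42 abundant Th1 genes and right the 115 Th1-high genes called higher in KO TFH cells, black lines are medians, and values beyond -40 or 160 are drawn at those limits. Abundant Th1 genes have medians of 6.41, 10.7 and 41.1 on arrays 1, 2 and 3, and the called genes 37.3, 45.9 and 54.4. The called genes were chosen for being higher on these arrays, and most of the 42 abundant genes are in both sets.

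The TFH program divided: 3 of 24 members rose, 5 fell and 16 did not pass (camera adjusted p = 0.193), with 3 and 9 when adjusted over the list alone. KO TFH array 3 may share in the falls. All 45 TFH-restricted genes, called at least 1.5 log2 units higher in WT TFH than in WT Th1 cells, were lower on it than their mean over arrays 1 and 2 (median -0.53). Il6st, the signalling chain of the IL-6 receptor, fell by 1.19 (adjusted p = 0.00204) and Id3 fell by 0.96 (adjusted p = 0.00642), while Il4, the helper cytokine IL-4, rose by 0.85, a call lost without WT TFH array 1 (adjusted p = 0.055). Il6st and Id3 lost theirs with KO TFH arrays 1 and 3 left out (adjusted p = 0.0585 and 0.0677). Il6ra, which binds IL-6, was at -0.59 (adjusted p = 0.0681), Il21, the TFH cytokine IL-21 (17404888), at 0.64 (adjusted p = 0.228). Icos, a co-stimulatory receptor, was at -0.15 (adjusted p = 0.323), and Pdcd1, the inhibitory receptor PD-1, at 0.37 (adjusted p = 0.185). Of 15 memory and quiescence genes, 5 fell and none rose (camera adjusted p = 0.00087, and adjusted p = 0.277 with an estimated correlation; 6 fell when adjusted over the list alone). The list lost its call with dim genes left out (adjusted p = 0.096) and with shared members left out (mean -0.245, adjusted p = 0.156). Ccr7, the lymph node homing receptor, fell by 1.23 (adjusted p = 5.08e-05), and Myb, a regulator of memory cells, fell by 0.99, a call lost without WT TFH array 1 or 3 (adjusted p = 0.0847 and 0.0616). With the mean of its probe sets Myb was at -0.46. Lef1, the factor most related to TCF1 (17402662), was at 0.18 (adjusted p = 0.252). Of 11 canonical Wnt targets, 1 fell and none rose (camera adjusted p = 0.565; 2 fell when adjusted over the list alone). It was Axin2, a feedback inhibitor of Wnt signalling, at -0.65, which lost its call with the mean of its probe sets (-0.18, adjusted p = 0.311).

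Some genes of other CD4 subsets and of migration were higher as well in KO TFH cells, several of them members of more than 1 list. Of 7 Th2 genes 2 rose, of 10 Th17 genes 4 rose, of 10 Treg genes 2 rose, and none of these fell. Adjusted over the list alone, 3, 4 and 4 rose. The camera adjusted p was 0.000606, 0.000588 and 0.0011, and with an estimated correlation the adjusted p was 0.0939, 0.127 and 0.0939. With shared members left out the Th2 mean fell from 0.61 to 0.21 (adjusted p = 0.134) and the Treg mean from 0.35 to 0.14 (adjusted p = 0.204), so both calls rest on shared genes, while Th17 genes stayed past the threshold (0.47, adjusted p = 0.0115). Without the arrays numbered 2 the Treg list lost its call too (adjusted p = 0.0681). The genes called include Ccr8 and Il4 among Th2 genes, Ccr6, a chemokine receptor of Th17 cells, at 1.44 (adjusted p = 3.37e-05), and Il2ra among Treg genes. Of 23 chemokine and homing receptors, 6 rose, with Ccr8, Cxcr6 and Ccr6 among them, and 1, Ccr7, fell (camera adjusted p = 0.000671, and adjusted p = 0.152 with an estimated correlation; 9 rose and 2 fell when adjusted over the list alone). That list lost its call with shared members left out (mean 0.40, adjusted p = 0.0535) and without the arrays numbered 2 (adjusted p = 0.059). Itga1, a collagen-binding integrin, rose by 1.79, but by 1.16 without KO TFH array 3, and its call was lost without WT TFH array 1 or 2 (adjusted p = 0.0778 and 0.058). Of 19 co-stimulatory and co-inhibitory receptors, 6 rose and none fell (camera adjusted p = 0.00351, and adjusted p = 0.277 with an estimated correlation; 8 rose and 2 fell when adjusted over the list alone), a list call lost without KO TFH array 2 (adjusted p = 0.109) and without the arrays numbered 2 (0.0824). One of them, Cd160, an inhibitory receptor, rose by 0.77 and lost its call without WT TFH array 1 (adjusted p = 0.0541).

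Of the remaining lists in KO against WT TFH cells, only cell cycle genes passed as a set. None of 25 cell cycle genes was called, and the list was lower (mean -0.14, camera adjusted p = 0.0311, and adjusted p = 0.851 with an estimated correlation). That set call was lost without WT TFH array 2 (adjusted p = 0.265), without KO TFH array 3 (adjusted p = 0.318), after quantile normalization (adjusted p = 0.39), after cyclic loess (0.805), with dim genes left out (0.741), with fry (0.526), with shared members left out (0.0514), without KO TFH arrays 1 and 3 (0.853) and without the arrays numbered 2 (0.0602). Of 28 cytokine receptor and STAT genes, 3 rose and 2 fell (camera adjusted p = 0.811; 3 and 4 when adjusted over the list alone), with Il2ra highest and Il6st lowest. No gene was called among 22 interferon response, 22 TCR-induced early and 18 glycolysis and HIF genes (limma, with 5258 of all genes at an unadjusted p under 0.05; camera adjusted p = 0.519, 0.8 and 0.297), and 1 of 14 apoptosis regulators, Fasl, rose (camera adjusted p = 0.851). The interferon list was higher after quantile normalization (mean 0.16, adjusted p = 0.0176). Among markers of other cells, 1 of 14 B cell genes fell (Cd22, a B cell receptor inhibitor, at -1.07, lost with KO TFH arrays 1 and 3 left out, adjusted p = 0.172), 1 of 5 CD8 T and NK genes fell (Cd8b1), and none of 6 plasma cell or 17 myeloid and dendritic genes was called, nor was the 1 erythroid gene measured. The camera adjusted p was 0.547 for B cell, 0.565 for CD8 T and NK, 0.957 for plasma cell and 0.534 for myeloid markers.

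**Figure D2:**
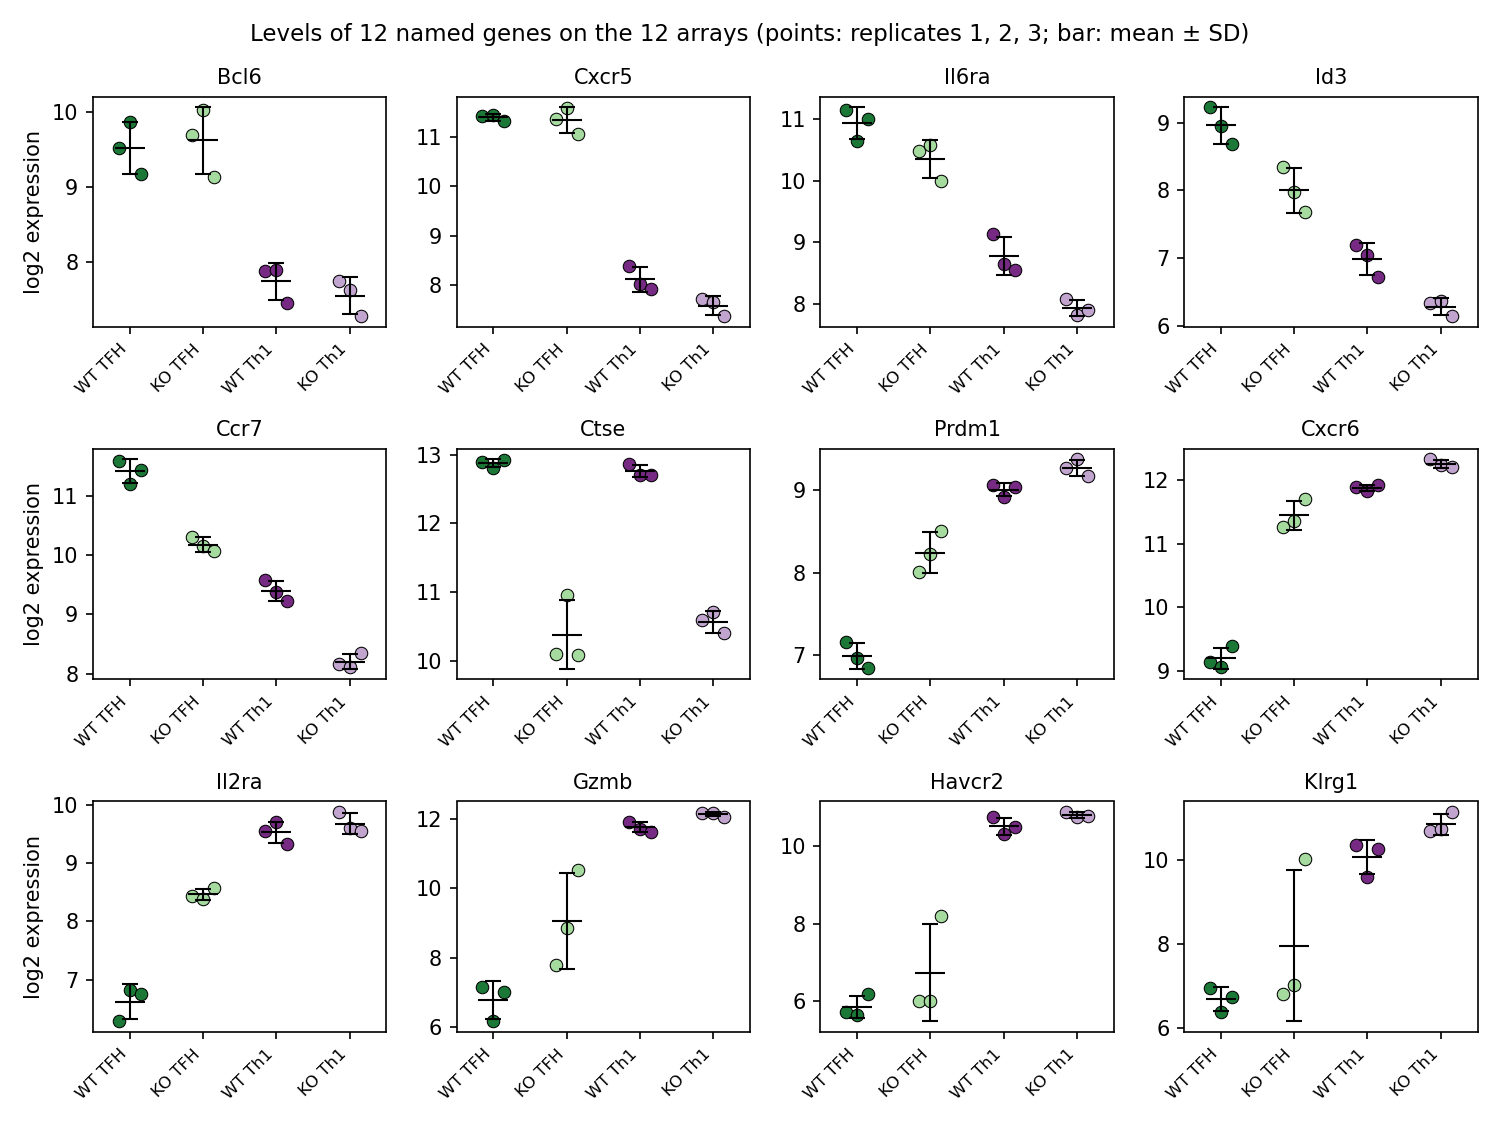
Expression of 12 genes on each array (y axis, log2 RMA value) in the 4 groups (x axis); each point is 1 replicate, and bars show the group mean ± SD (n = 3). Bcl6 and Cxcr5 have like levels in WT and KO TFH cells, Cxcr6, Il2ra and Prdm1 are higher in KO than in WT TFH cells, and the 3 KO TFH arrays differ widely for Gzmb (7.80, 8.87 and 10.54).

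The second comparison asked the same of Th1 cells, where few genes passed. Ctse fell from 12.76 ± 0.09 to 10.57 ± 0.16 (SD, n = 3), and Ccr7 from 9.39 ± 0.18 to 8.21 ± 0.12 (SD, n = 3). Lamc1 rose from 8.70 ± 0.10 to 9.70 ± 0.10, and Csf1, the growth factor of macrophages, from 7.30 ± 0.22 to 8.55 ± 0.50 (SD, n = 3). Genes of Th1 function did not pass: Tbx21 was at a log2 difference of 0.14 (adjusted p = 0.962), Ifng at 0.22 (adjusted p = 0.895), Gzmb at 0.38 (adjusted p = 0.969) and Prdm1 at 0.26 (adjusted p = 0.714).

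With limma and Benjamini-Hochberg adjustment, 12 genes were called in Th1 cells, 5 higher and 7 lower in KO, all without overlap between the groups, and 1552 had an unadjusted p under 0.05. Over all genes 14.1% had no overlap, where chance gives 10%. The falls were Ctse at -2.19 (SE 0.18, adjusted p = 4.95e-05), A430107P09Rik, named after its values were seen, at -1.98, Cd8b1 at -1.33 and Ccr7 at -1.19 (adjusted p = 0.000492). Sestd1 was at -1.09, Slamf6, a receptor of the SLAM family, at -0.58, and Il2, the growth factor IL-2, at -0.49. Il2 was dim, at 5.11 in WT and 4.62 in KO Th1 cells, under the array medians of 6.44 to 6.55. The rises were Csf1 at 1.25, Lamc1 at 1.0 (adjusted p = 0.000492), Fgl2, a secreted inhibitor of T cells, at 0.92, Dse, an enzyme of dermatan sulfate synthesis, at 0.89, and Crim1 at 0.80. With the replicate number as a block, 42 genes were called (10 higher, 32 lower), including all of these 12. Among the others were Id3 at -0.71 (adjusted p = 0.00874, against 0.206 without the block), and Il6ra at -0.85 (adjusted p = 0.0304, against 0.128). Named after their values were seen, Ccr8 was at 1.08 (adjusted p = 0.00874) and Crtam, an adhesion receptor of cytotoxic cells, at -0.84 (adjusted p = 0.00874). The count was 6 without WT Th1 array 1, WT Th1 array 2 or KO Th1 array 3, 7 without WT TFH array 1, 20 without WT Th1 array 3, 22 without KO TFH array 2 and 23 without KO TFH array 3. Ctse, Lamc1, Cd8b1 and Ccr7 were called whichever array was left out. With the arrays numbered 2 left out Ctse remained called, while Lamc1, Cd8b1 and Ccr7 did not (adjusted p = 0.152, 0.238 and 0.0732). Fgl2 lost its call without KO Th1 array 1 (adjusted p = 0.0556). Sestd1 lost it without WT Th1 array 1, KO Th1 array 2, WT Th1 array 2 or KO Th1 array 3 (adjusted p = 0.054, 0.055, 0.0554 and 0.0745). Csf1, Dse, Crim1, Slamf6 and Il2 each lost theirs without KO Th1 array 1 or 3, WT TFH array 1, or WT Th1 array 1 or 2, and without further arrays (highest adjusted p 0.172, 0.145, 0.131, 0.212 and 0.212).

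As sets, TFH genes and cell cycle genes were lower in KO than in WT Th1 cells, but so were markers of other cells: myeloid and dendritic (mean -0.25, camera adjusted p = 0.000728) and plasma cell markers (mean -0.31, camera adjusted p = 0.021), with adjusted p of 0.431 and 0.298 with an estimated correlation. In the TFH program 1 of 24 fell, Slamf6, and none rose (mean -0.32, camera adjusted p = 9.42e-12, and adjusted p = 0.165 with an estimated correlation; 7 fell when adjusted over the list alone). Bcl6 was at -0.19 (adjusted p = 0.964) and Cxcr5 at -0.53 (adjusted p = 0.318). Il21 was at -0.22 (adjusted p = 0.973), Icos at -0.21 (adjusted p = 0.694) and Pdcd1 at 0.06 (adjusted p = 0.988). None of 25 cell cycle genes was called, but their mean was -0.28 (camera adjusted p = 1.74e-14, and adjusted p = 0.16 with an estimated correlation). With fry neither list passed (adjusted p = 0.0932 and 0.0888). Among memory and quiescence genes 2 of 15, Ccr7 and Slamf6, fell (camera adjusted p = 0.291; 4 fell when adjusted over the list alone), and Lef1 was at 0.21 (adjusted p = 0.692). Among Th1 program genes none of 23 was called (mean 0.10, camera adjusted p = 0.0607, and 0.0318 after quantile normalization). None of 18 cytotoxic genes was called, with a mean of 0.28 (camera adjusted p = 0.0191, and adjusted p = 0.794 with an estimated correlation), and the set was not past the threshold without KO Th1 array 1, WT Th1 array 2 or WT Th1 array 3 (adjusted p = 0.161, 0.318 and 0.0561), without the arrays numbered 2 (0.0911), with fry (0.587) or with shared members left out (0.51).

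The third comparison set TFH against Th1 cells of WT mice, as the reference for the subset difference. TFH cells were higher in most TFH program genes: Cxcr5 stood at 11.39 ± 0.07 in TFH and 8.12 ± 0.25 in Th1 cells (SD, n = 3), Bcl6 at 9.52 ± 0.35 and 7.75 ± 0.24, and Il21 at 10.30 ± 0.52 and 8.76 ± 0.52 (SD, n = 3). Th1 cells were higher in most cytotoxic and Th1 program genes: Gzmb was 11.76 ± 0.15 in Th1 and 6.78 ± 0.54 in TFH cells, and Cxcr6 was 11.88 ± 0.05 and 9.19 ± 0.17 (SD, n = 3). Cell cycle genes were also higher in Th1 cells.

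With limma and Benjamini-Hochberg adjustment, 1747 genes were called, 838 higher and 909 lower in TFH cells, and 397 differed at least 2-fold (119 higher, 278 lower). Of the calls, 1746 had no overlap. Over all genes 24.1% had none, where chance gives 10%. The rises were led by Cxcr5 at 3.28 (SE 0.15, adjusted p = 1.22e-08), Sostdc1, a secreted inhibitor of Wnt and BMP signals, at 3.10, and Nsg2 at 2.89. Nt5e, the ectoenzyme CD73, was at 2.37, Ccr6 at 2.32, Ephx1, an epoxide hydrolase, at 2.17, and Il6ra at 2.16. Izumo1r, the folate receptor FR4, was at 2.07, Il23r, the IL-23 receptor, at 2.04, and Fam43a at 2.01 (adjusted p of the 10 up to 0.0015). Bcl6 was at 1.77 (SE 0.21, adjusted p = 5.81e-05), Id3 at 1.97, Il21 at 1.54 (adjusted p = 0.00486) and Pdcd1 at 0.79 (adjusted p = 0.00522). The falls were led by Gzmb at -4.98 (SE 0.46, adjusted p = 4.69e-06), Havcr2, the inhibitory receptor TIM-3, at -4.65, and Ccl3, a chemokine that attracts myeloid cells, at -4.06. Ccr2, a receptor for inflammatory chemokines, was at -3.63, Itgax, the integrin CD11c, at -3.48, and Itga1 at -3.45. Klrg1, a receptor of terminal effector cells, was at -3.37, Il2ra at -2.90, F2rl2, a thrombin receptor, at -2.80, and Itgam, the integrin CD11b, at -2.73 (adjusted p of the 10 up to 0.00132). Prdm1 was at -2.01, Tbx21 at -1.0 (adjusted p = 0.000418) and Ifng at -0.69 (adjusted p = 0.00951), the last lost without WT Th1 array 1 or WT TFH array 3 (adjusted p = 0.0519 and 0.0561). Icos was at 0.30 (adjusted p = 0.0616).

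By list, 19 of 24 TFH program genes rose and 1 fell (camera adjusted p = 1.49e-24, and 21 and 2 when adjusted over the list alone). The 1 that fell was Maf, a transcription factor of several helper subsets, named after its values were seen, at -0.70. Of 23 Th1 program genes 19 fell (camera adjusted p = 2.42e-26, and 1 rose and 19 fell when adjusted over the list alone). Of 18 cytotoxic genes 12 fell and 1 rose (camera adjusted p = 1.11e-14, and 14 and 1 when adjusted over the list alone). Of 25 cell cycle genes 24 fell (camera adjusted p = 5.47e-43, and 25 when adjusted over the list alone), with Bub1, a spindle checkpoint kinase, at -1.95, Birc5, survivin, at -1.84, and Ccna2, cyclin A2, at -1.67. Of 15 memory and quiescence genes 6 rose (camera adjusted p = 4.33e-10, and 10 when adjusted over the list alone), with Ccr7 at 2.01 among them. With an estimated correlation the adjusted p was 0.0939 for each of these lists except the cytotoxic list, at 0.133. None of the 38 list calls of the 5 comparisons held with an estimated correlation, where the lowest adjusted p was 0.0939.

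The fourth comparison asked what remains of this difference without TCF1. KO TFH cells still stood far from KO Th1 cells in Cxcr5 (11.33 ± 0.27 against 7.59 ± 0.19), Bcl6 (9.62 ± 0.44 against 7.56 ± 0.24) and Il21 (10.94 ± 0.44 against 8.55 ± 0.51; SD, n = 3). Since FACS parted the subsets in both genotypes, such distances may in part be set by the sort. Cxcr6 stood at 11.45 ± 0.23 against 12.26 ± 0.06, a shorter distance than in WT cells (interaction adjusted p = 0.000269), and Il2ra at 8.47 ± 0.09 against 9.67 ± 0.18 (SD, n = 3; interaction adjusted p = 0.00228). Cell cycle genes were again higher in Th1 cells.

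With limma and Benjamini-Hochberg adjustment, 2488 genes were called, 731 higher and 1757 lower in KO TFH than in KO Th1 cells, and 351 differed at least 2-fold (109 higher, 242 lower). Of the calls, 2441 had no overlap, and 26.4% of all genes had none, where chance gives 10%. The lower share depended on scaling and arrays: 70.6% of the calls were lower, against 63.8% of 2234 after quantile normalization, 63.3% of 2199 after cyclic loess, 80.6% of 2664 after median centring and 55.7% of 1383 without KO TFH arrays 1 and 3. The count was 1543 without KO TFH array 1, 1560 without KO Th1 array 1 and 1383 with KO TFH arrays 1 and 3 left out. Rises were led by Ccr6 at 3.77 (SE 0.14, adjusted p = 1.11e-09), Cxcr5 at 3.74, Sostdc1 at 3.54, Il23r at 3.17 and Nt5e at 2.78. Il1r2, a decoy receptor for IL-1, was at 2.55, Igf1r, the IGF-1 receptor, at 2.51, Ntrk3, a neurotrophin receptor, at 2.45, Il6ra at 2.43 and Il21 at 2.40 (adjusted p = 0.000143). Bcl6 was at 2.06 (adjusted p = 1.89e-05) and Pdcd1 at 1.11. Falls were led by Havcr2 at -4.07, Itgam at -3.13, Itgax at -3.07, Gzmb at -3.06 (SE 0.46, adjusted p = 0.000449), and Klrg1 at -2.90. Ccl3 was at -2.82, Ccr2 at -2.56, Med7, a Mediator subunit, at -2.46, H1f5, a linker histone, at -2.42, and Itga1 at -2.40. Med7 was at -1.28 with the mean of its probe sets, and Klrg1 lost its call with the arrays numbered 2 left out (adjusted p = 0.0676). Icos was at 0.36, lost without KO Th1 array 2 (adjusted p = 0.0841), and Ifng at -0.38 (adjusted p = 0.128).

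By list in KO cells, 20 of 24 TFH program genes rose and none fell (camera adjusted p = 2.42e-26, and 22 when adjusted over the list alone). Of 23 Th1 program genes 15 fell and 2 rose (camera adjusted p = 5.22e-11, and 18 and 3 when adjusted over the list alone). Of 18 cytotoxic genes 13 fell and 1 rose (camera adjusted p = 1.39e-10, and 16 and 1 when adjusted over the list alone). Of 25 cell cycle genes 23 fell (camera adjusted p = 1.94e-29, and 24 when adjusted over the list alone). Of 15 memory and quiescence genes 5 rose and 2 fell (camera adjusted p = 0.00316, and 6 and 2 when adjusted over the list alone). Of 10 Th17 genes 3 rose (camera adjusted p = 0.0055, and 3 when adjusted over the list alone). With an estimated correlation the adjusted p of these 6 lists was 0.0939, 0.132, 0.162, 0.0939, 0.357 and 0.152. With shared members left out the mean of memory and quiescence genes fell from 0.36 to 0.007 (adjusted p = 0.792) and that of Th17 genes from 0.94 to 0.62 (adjusted p = 0.156). The first list lost its call without the arrays numbered 2 as well (adjusted p = 0.0985), and the second without KO TFH arrays 1 and 3 (adjusted p = 0.103).

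Of the genes called between WT TFH and WT Th1 cells, 94.6% had the same direction in KO cells: 770 of 838 TFH-high and 883 of 909 Th1-high genes. This share describes cells already sorted into the subsets. In KO cells 390 and 729 of them were called. The median difference of the TFH-high genes was 0.55 in WT and 0.37 in KO cells, a ratio of 0.66, and that of the Th1-high genes was -0.67 and -0.64, a ratio of 0.95. Genes chosen on 2 WT replicate numbers and measured on the third gave mean ratios of 0.73 and 0.88. These were smaller sets, of 396 TFH-high and 567 Th1-high genes on average. Their WT medians were 0.78 and -0.97 on the arrays of the choice and 0.74 and -0.96 on the third. Selection thus inflated their WT medians little, and these ratios are not those of the 838 and 909 genes with selection removed. With KO TFH arrays 1 and 3 left out the TFH-high ratio was 0.93, and no p-value was computed across genes. Other alternatives, given below, put this ratio under as well as over 0.66. All 45 TFH-restricted genes were lower on KO TFH array 3 than their mean over arrays 1 and 2 (median -0.53), which lowers the TFH-high difference in KO cells.

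**Figure D3:**
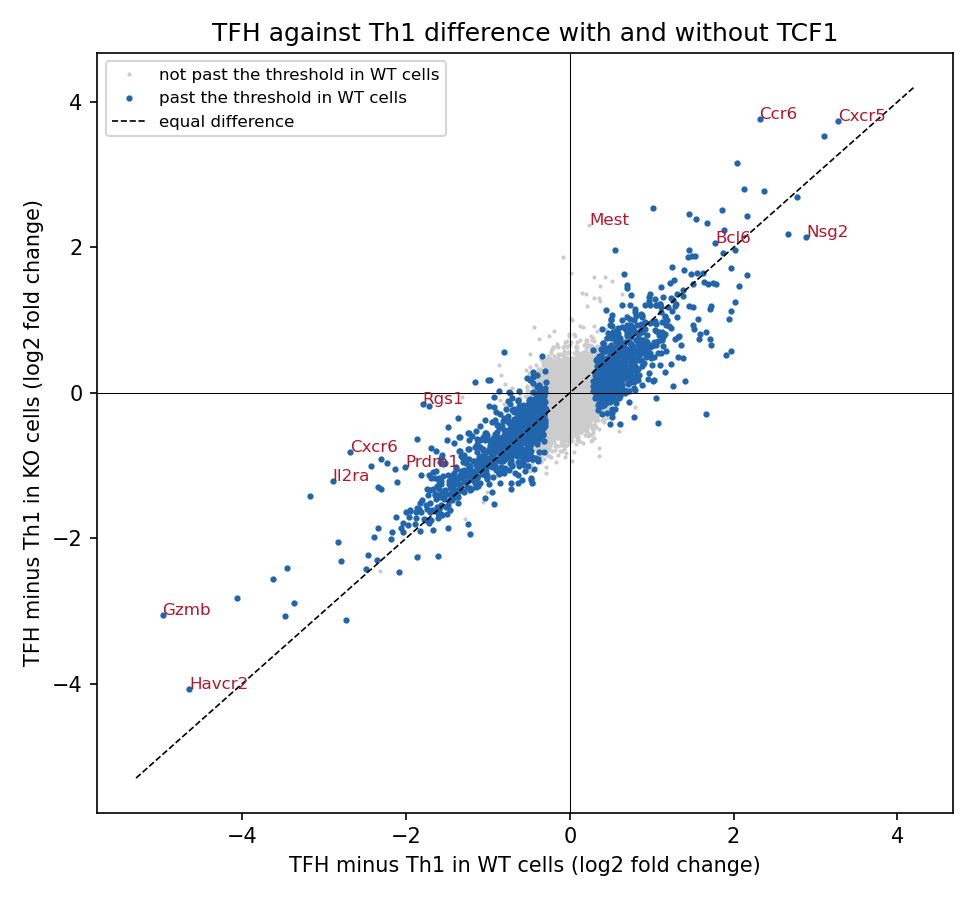
TFH minus Th1 log2 difference of each gene in WT cells (x axis) and in KO cells (y axis); blue points were called in WT cells, and the dashed line marks equal differences. Cxcr5 (3.28 and 3.74) and Bcl6 (1.77 and 2.06) lie near the line, while Cxcr6 and Il2ra lie above it, with a smaller difference in KO cells.

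The interaction tested whether the genotype effect differed between the subsets, and 33 genes passed (limma, Benjamini-Hochberg), 25 with a higher and 8 with a lower effect in TFH cells, while 2599 had an unadjusted p under 0.05. Cxcr6 had a higher KO minus WT difference in TFH than in Th1 cells, by a log2 value of 1.88 (SE 0.16, adjusted p = 0.000269), as did Il2ra by 1.69, Ccl5 by 1.54, Ccr6 by 1.46 and Mest by 2.08. For Bcl6 (0.29, adjusted p = 0.708), Cxcr5 (0.47, adjusted p = 0.405), Id3 (-0.25, adjusted p = 0.682), Il6ra (0.26, adjusted p = 0.676) and Gzmb (1.91, adjusted p = 0.318) no difference between the subsets was detected. By list, 5 of 23 Th1 program genes passed, all with a higher effect in TFH cells (mean 0.53, camera adjusted p = 2.32e-10, and adjusted p = 0.133 with an estimated correlation; 7 higher and 1 lower when adjusted over the list alone). After median centring 25 genes passed, 64% of them higher, against 75.8%. With the replicate number as a fixed block 66 passed, 47 higher and 19 lower, and with the random block 84 passed, 42 higher and 42 lower. The count was 16 to 20 without KO Th1 array 1, 2 or 3, WT TFH array 1 or 3, or WT Th1 array 1, 2 or 3 (18, 18, 16, 19, 16, 20, 17 and 17), and 338 without KO TFH array 2, with 21.9% higher. It was 15 with KO TFH arrays 1 and 3 left out and 1 with the arrays numbered 2 left out, where Cxcr6 had an adjusted p of 0.0521.

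Across genes, the genotype effects in TFH and Th1 cells correlated at r = 0.30 (Pearson) and 0.16 (Spearman), where genes are not independent replicates. Without WT Th1 array 1 the Pearson value was 0.189, and without KO Th1 array 3 it was 0.169. Of the 12 genes called in Th1 cells, 11 were also called in TFH cells, 4 higher and 7 lower in both, where independent lists would share 0.066 and 0.24, and none was opposite. That expectation leaves out that samples of the same number share some of their spread. In a test chosen after the data were seen, effects of single arrays correlated at a mean r of 0.26 between TFH and Th1 cells of the same number (0.18 to 0.35) and 0.14 between different numbers (-0.08 to 0.27), so part of r may come from the pairing. The 11 shared genes are Csf1, Dse, Fgl2 and Lamc1, higher, and Ctse, Ccr7, Cd8b1, Sestd1, Slamf6, Il2 and A430107P09Rik, lower. In TFH cells Csf1 was at 1.79 and Ctse at -2.49, and Il2 was dim in both subsets. Of the genes called in TFH cells, 220 of 293 higher and 562 of 761 lower ones had the same sign in Th1 cells, with medians of 0.11 and -0.10 there against 0.54 and -0.49.

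Genes higher in KO TFH cells were often Th1-high in WT cells. Of the 293, 115 were Th1-high, where independent lists would share 12, and 11 were TFH-high (11.1). Of the 761 lower genes, 232 were TFH-high (28.8) and 19 were Th1-high (31.2). KO TFH array 3, which may hold Th1 cells, takes part in these counts: 68 of the 115 genes were called without it. All 45 TFH-restricted genes were lower on it than their mean over arrays 1 and 2. Of all 1054 calls, 318 were kept without that array, 264 without WT TFH array 1 and 1025 without KO TFH array 2. The loss of calls is therefore not particular to the 115 genes. Both comparisons use the WT TFH arrays, and data simulated without effects gave r = -0.50 across genes between the pair of comparisons, against -0.40 observed, so r alone shows no relation, while the covariance was -0.029 against a simulated mean of -0.0094. The overlap was therefore counted again, in a test chosen after the data were seen, with 1 WT TFH array in one comparison and the other 2 in the other. Over the 6 ways to do so, 34 to 59 genes higher in KO TFH cells were Th1-high, where independent lists would share 1.63 to 4.84, and 23 to 70 lower genes were TFH-high (0.90 to 6.42). In each of these fits 1 WT TFH array stands alone in a comparison and is assumed to vary like the other groups, so the counts show an excess without shared arrays under that assumption only, and KO TFH array 3 is in all of them.

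**Figure D4:**
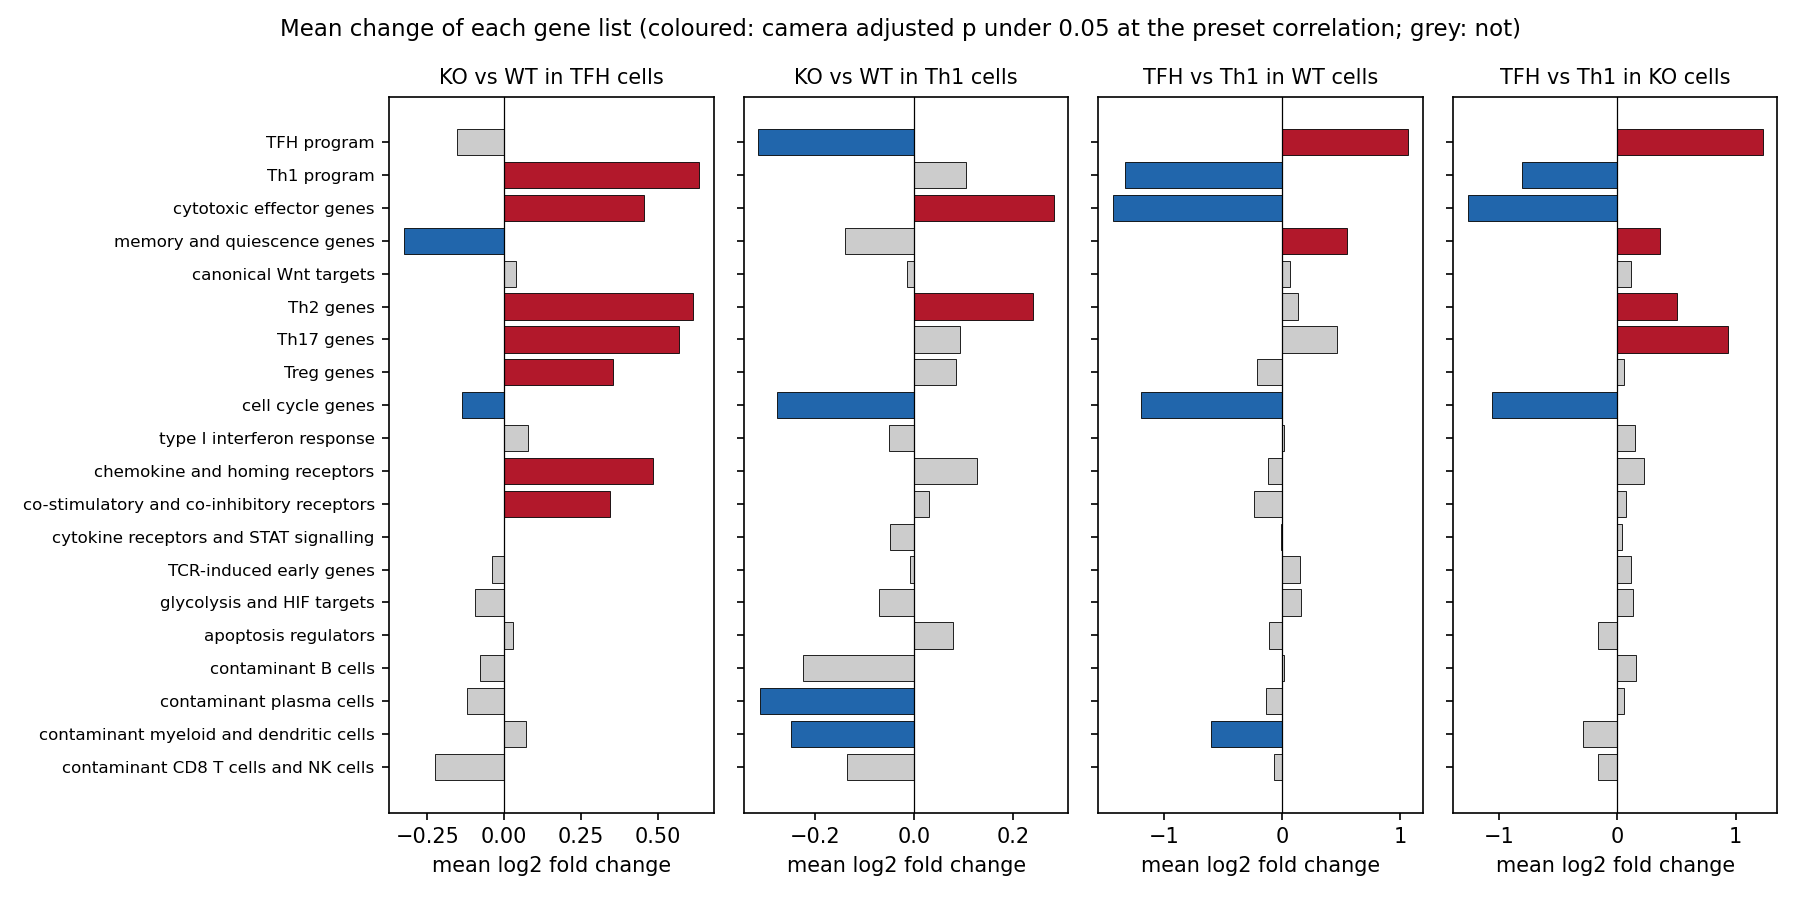
Mean log2 change of the members of each gene list (x axis, scales differ between panels) in the 4 group comparisons; red and blue bars mark lists higher and lower at a camera adjusted p under 0.05 with the preset correlation, and grey bars the others. The Th1 program is higher in KO than in WT TFH cells (mean 0.63), and cell cycle genes are lower in TFH than in Th1 cells of both genotypes (-1.19 and -1.06).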

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

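The interaction test, its gene lists, their alternatives with 1 array or shared members left out and the counts over other splits of the arrays were planned. The fits without the arrays numbered 2 and without KO TFH arrays 1 and 3, and the tests of both patterns below, those of Th1 cells among sorted TFH cells and of the range of values, were chosen after the result was seen.

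The genotype effect differed between TFH and Th1 cells, by the interaction test, for 33 genes (limma, Benjamini-Hochberg). Of those named, the effect was higher in TFH cells for Mest (log2 difference of effects 2.08), Susd2 (1.95), Cxcr6 (1.88), Il2ra (1.69), Ccl5 (1.54), Ccr6 (1.46), Dennd5a (1.43), Itgb8 (1.42), Pik3ap1 (1.39), Ifi204 (1.36), Prdm1 (0.99) and Il12rb2 (0.84). It was lower for Esm1 (-1.95), Pde2a (-1.49), Tuba8 (-1.38), Kif1b (-1.26), Slc28a2b (-1.16), Camsap2 (-0.84), Lactb (-0.81) and Ggct (-0.74). Mest, Cxcr6, Il2ra, Ccl5, Ccr6, Dennd5a, Itgb8, Pik3ap1 and Pde2a kept their calls whichever array was left out. The other 11 lost theirs without WT TFH array 3 (adjusted p 0.0593 to 0.118) and without 2 or more further arrays, and Prdm1 without any of 9 arrays (adjusted p 0.0584 to 0.114). With the arrays numbered 2 left out only 1 gene was called.

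Gene lists whose genotype effect differed between the subsets by camera were the Th1 program (mean log2 difference of effects 0.53), Th17 genes (0.48), Th2 genes (0.37), chemokine and homing receptors (0.35), myeloid and dendritic markers (0.32), co-stimulatory and co-inhibitory receptors (0.31), Treg genes (0.27), the TFH program (0.16), cell cycle genes (0.14) and memory and quiescence genes (-0.19). Each lost its call with an estimated correlation, with adjusted p from 0.133 to 0.839. The calls of the Th1, Th17 and chemokine lists were kept whichever array was left out, but with shared members left out Th17 genes (0.37, adjusted p = 0.0689), chemokine receptors (0.24, 0.287), Th2 genes (0.10, 0.457), Treg genes (0.07, 0.685) and memory and quiescence genes (-0.23, 0.0629) lost theirs. The Th1 program lost its call with the estimated correlation alone. Without the arrays numbered 2 the calls of the TFH program, Th2 and Treg genes were lost (adjusted p = 0.189, 0.0616 and 0.297). With fry those of the TFH program, cell cycle genes, memory and quiescence genes, co-stimulatory receptors and myeloid markers were lost (0.0668 to 0.587). The TFH program lost its call without WT Th1 array 1, KO TFH array 2, KO Th1 array 3 or WT TFH array 3 (adjusted p = 0.178, 0.425, 0.0572 and 0.109), co-stimulatory receptors without KO TFH array 2 (0.0918), and myeloid markers without WT Th1 array 2, KO TFH array 3 or WT TFH array 3 (0.065, 0.11 and 0.0508). Th2 genes lost theirs without WT TFH array 2 or WT Th1 array 3 (0.0709 and 0.0535), and Treg genes without WT Th1 array 1, KO TFH array 2, KO Th1 array 2 or WT TFH array 2 or 3 (0.0512 to 0.183). Cell cycle genes lost theirs without WT TFH array 1, KO TFH array 2, WT Th1 array 2 or KO Th1 array 3 (0.0592 to 0.496). Memory and quiescence genes lost theirs without KO Th1 array 1 or 3, KO TFH array 2 or 3, WT Th1 array 2 or WT TFH array 3 (0.0516 to 0.0969). They lost it with dim genes left out (0.295) and after cyclic loess (0.213) too. With array weights the TFH program, Treg and cell cycle genes lost theirs (0.317, 0.119 and 0.154). With KO TFH arrays 1 and 3 left out the means of memory and quiescence genes and of myeloid markers were -0.18 and 0.14.

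For each group comparison the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 of 10, the real split, reached the real count. In KO against WT TFH cells the real split gave 1054 genes and the highest other split 0, in KO against WT Th1 cells 12 and 0, in WT TFH against WT Th1 cells 1747 and 0, and in KO TFH against KO Th1 cells 2488 and 0. For KO against WT Th1 cells and WT TFH against WT Th1 cells, whose numbers pair the samples, the other 3 splits that part all pairs gave 0 genes as well. For the interaction, 8 of 100 drawn splits (of 200 possible) gave at least the 33 genes of the real split, and the highest other split gave 213, so these splits do not exclude chance. Nor do they speak for it: all 7 others kept the TFH arrays in their true genotype groups and so carry the genotype effect of TFH cells, a structure of the samples to which 213 genes point. Among the drawn splits that mixed the TFH arrays the highest count was 11. A split that mixes groups puts their difference into the spread within groups, which lowers its count. The low counts of 0 and 11 therefore do not bear on chance.

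First pattern: 115 genes that are Th1-high in WT cells were higher in KO TFH cells, and Th1 cells left among the sorted TFH cells would bring all their abundant transcripts. On KO TFH arrays 1 and 2 the 42 abundant Th1 genes stood at 7.73% (95% bootstrap interval over genes 4.42 to 24.4) of the way to the KO Th1 level. The 115 genes stood at 41.6% (36.8 to 47.8), and the 76 of them with at least 1 log2 unit between the groups at 33.1% (27.3 to 39.4). Part of this gap is built in, since the 115 genes were chosen for being higher on these arrays. The sets are not separate. Most of the 42 abundant genes are among the 115 too, such as Cxcr6 (43.4% and 47.3%). Those outside the 115, such as Havcr2 (0.316% and 0.351%), ran from -16.6% (Irak3) to 6.99% (Lair1) on array 1. On array 2 they ran from -10.1% (Irak3) to 16.8% (Lair1), but they are by choice the genes not called higher. As a whole, the 42 abundant genes were chosen without their KO TFH levels, and their interval holds no Th1 share over 24.4% on arrays 1 and 2. That upper bound, which rests in part on genes of both sets, lies below the level of the 115 genes. Given their choice, Th1 cells as a partial cause stay open there too. On array 3 the values were 41.1% (38.6 to 45.3) and 54.4% (50.2 to 59.4), but over the 76 genes 48.1% (42.3 to 51.2), so the intervals overlap, and the genes were chosen for being higher on these arrays. Th1 cells as the cause on array 3 therefore stay open. All 45 TFH-restricted genes were lower on array 3 than their mean over arrays 1 and 2 (median -0.53, interval -0.64 to -0.47). An added Th1 share of 33.4% predicts -0.39, a smaller fall than that interval holds, so this share alone does not give the fall. Th1 cells on array 3 may still account for part of its values despite the FACS sort. Without that array 68 of the 115 genes were called, and 318 of all 1054 calls were kept. The narrower range of arrays 1 and 3 is argued against by the 104 of 115 genes still called after quantile normalization. For the 115 genes as a set, the values on arrays 1 and 2 argue against Th1 cells as the whole cause there. Th1 cells as a partial cause there and as the cause on array 3 stay open, as does an effect of TCF1 deficiency.

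Second pattern: 72.2% of the genes called in KO TFH cells were lower. With KO TFH arrays 1 and 3 left out, whose values span a narrower range, 32.1% of 131 calls were lower, as that range would give, but only 1 KO TFH array remains in that fit. After repeated quantile normalization 62.0% of 718 calls (binomial interval over genes 58.3 to 65.5) were still lower, and after cyclic loess 60.6% of 709. Without array 3, 59.8% of 331 calls (54.3 to 65.1) were lower. With dim genes left out it was 78.8% of 1756 calls. Lower calls thus stayed the larger part in these fits. The intervals treat called genes as independent and do not measure the spread between arrays. They therefore do not decide whether the range or Th1 cells on array 3 are the whole cause. Both may account for some of the excess, and a genotype effect stays open.

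Probe sets without a single gene name (16010 with none, 1814 with several), which the gene comparisons did not use, also differed between groups: of 17824 such probe sets, 179 were called in KO against WT TFH cells (100 higher, 79 lower) and 35 in KO against WT Th1 cells (17 higher, 18 lower). Between TFH and Th1 cells 254 were called in WT and 602 in KO cells, and 1 in the interaction.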

How the results depend on the processing

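The sex term, the fits that leave out KO TFH arrays 1 and 3 or the arrays numbered 2, and those that part the numbers or WT TFH arrays were chosen after the data were seen; all others were planned. Main counts were 1054 (KO against WT TFH), 12 (KO against WT Th1), 1747 (TFH against Th1, WT), 2488 (TFH against Th1, KO), 33 (interaction) and 38 list calls. The WT TFH against Th1 count stayed within 1.5 times under every alternative (1207 to 1988 with 1 array left out). Where other counts moved further, the cause was not tested unless fewer genes or arrays show it. KO against WT TFH gave 551 probe sets, not genes, with every probe set tested, 1756 genes with dim genes left out, 2380 with array weights, 373 in a fit to the compared groups only, 131 without KO TFH arrays 1 and 3, 2334 without the arrays numbered 2, and 267 to 3264 with 1 array left out. Of the 1054 genes, 644 were called again after quantile normalization, 605 after cyclic loess and 1025 without KO TFH array 2. KO against WT Th1 gave 48 probe sets with every probe set, 46 genes with array weights, 42 with the replicate block, 21 with the sex term, 38 without KO TFH arrays 1 and 3, 4 without the arrays numbered 2, and 6 to 23 with 1 array left out. TFH against Th1 in KO cells gave 1638 in a fit to the compared groups only, 1383 without KO TFH arrays 1 and 3, and 1543 to 3316 with 1 array left out.

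The interaction gave 12 probe sets with every probe set, 57 genes with dim genes left out, 50 with the trend and robust variances, 117 with array weights, 66 with the replicate block, 84 with the random block, 15 without KO TFH arrays 1 and 3, 1 without the arrays numbered 2, and 16 to 338 with 1 array left out. The replicate block, for the pairing, otherwise gave 1466, 1973 and 2782 genes in KO against WT TFH and in TFH against Th1 of WT and KO cells, 42 list calls, 93.9% kept direction and ratios of 0.667 and 0.973. List calls numbered 0 with an estimated correlation, 22 with shared members left out, 28 with fry, and 31 to 44 with 1 array left out. The share of genes with kept direction ran from 88.1% to 97.2% with 1 array left out, the TFH-high ratio from 0.462 to 0.797 (0.934 without KO TFH arrays 1 and 3), the Th1-high ratio from 0.859 to 1.01, and r between the genotype effects from 0.169 to 0.361. Ighm turned to -0.075 (adjusted p = 0.969) between WT TFH and Th1 cells with the mean of its probe sets, and TCR-induced early genes to -0.15 (adjusted p = 0.0187) in KO against WT Th1 cells without KO Th1 array 1 and 0.13 without WT Th1 array 1. Of the named genes called, 22 of 47, 1 of 11, 51 of 65, 55 of 69 and 1 of 20 kept their call under every alternative in the 5 comparisons. With dim genes left out, the median difference of the brighter genes that remain was -0.11 in KO against WT TFH cells, against 0.02 over all genes. No other alternative moved a median by over 0.1. Signal over background was not measured, so a change in a dim gene can lie under what these arrays show.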

Other observations

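The test on genes near Tcf7 was chosen after the main results were seen. Further gene groups were divided between TFH and Th1 cells. Of 23 chemokine and homing receptors, 6 rose and 7 fell in WT TFH against WT Th1 cells (camera adjusted p = 0.813), and 9 rose and 7 fell in KO cells (camera adjusted p = 0.41). Ccr6, Ccr7 and Cxcr5 were among the higher and Ccr2, Cxcr6 and Itga1 among the lower ones in WT TFH cells. Of 28 cytokine receptor and STAT genes, 6 rose and 7 fell in WT cells, with Il6ra at 2.16 and Il2ra at -2.90, and 5 rose and 7 fell in KO cells. Of 14 apoptosis regulators, 2 rose and 4 fell in WT cells, with Fas, the death receptor, at 1.05, Bcl2, which blocks apoptosis, at 0.88 (0.49 with the mean of its probe sets) and Fasl at -1.67. Of 18 glycolysis and HIF genes, 4 rose and 2 fell in WT cells, with Egln3, an oxygen sensor, at 1.87, Slc2a3, a glucose transporter, at -1.03 and Hk2, hexokinase, at -0.65. Of 22 TCR-induced early genes, 3 rose and 2 fell in WT cells, with Egr2 at 0.88 and Ier3 at -1.15. None of these lists was past the threshold as a set in WT or KO cells (camera adjusted p 0.109 to 0.813), nor was the interferon response, where 2 of 22 genes rose in WT cells and 4 rose and 1 fell in KO cells (camera adjusted p = 0.937 and 0.348).

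Other lists were past the threshold in Th1 cells or between the subsets. In KO against WT Th1 cells no member was called of 7 Th2 genes (mean 0.24, camera adjusted p = 0.021), 17 myeloid and dendritic markers (mean -0.25, camera adjusted p = 0.000728) or 6 plasma cell markers (mean -0.31, camera adjusted p = 0.021), with 1552 of all genes at an unadjusted p under 0.05 (limma). With the replicate number as a block, Ccr8 of the Th2 genes was called (1.08, limma adjusted p = 0.00874). With an estimated correlation the adjusted p of the 3 lists was 0.15, 0.431 and 0.298. Th2 genes lost their call without WT Th1 array 1, WT Th1 array 2 or KO Th1 array 3 (adjusted p = 0.0908, 0.0637 and 0.135), without the arrays numbered 2 (0.0571) and with shared members left out (0.335). Myeloid markers lost theirs without WT Th1 array 2 (0.0838), with dim genes left out (0.0695), without the arrays numbered 2 (0.309) and with fry (0.428), and plasma cell markers without KO Th1 array 1 or 3 or WT Th1 array 1 or 2 (0.0708 to 0.106) and with fry (0.226). In WT TFH against WT Th1 cells 3 of 17 myeloid markers fell, Itgax, Itgam and Cst3 (camera adjusted p = 0.00171, adjusted p = 0.499 with an estimated correlation, 0.0714 without WT Th1 array 2, and 0.121 with fry). Itgax and Itgam, at -3.48 and -2.73, encode integrins that activated T cells carry too, and Cst3, at -0.38, lost its call without WT TFH array 2 or 3 or WT Th1 array 2 or 3 (adjusted p 0.0566 to 0.116). In KO TFH against KO Th1 cells 3 of 7 Th2 genes rose and 1 fell (camera adjusted p = 0.0173, and adjusted p = 0.14 with an estimated correlation), a call lost with dim genes left out (0.0927) and with shared members left out, where the mean turned from 0.51 to -0.04 (0.871). Median and mean differed in sign in KO against WT TFH cells for cytokine receptors (-0.07 and 0.0007), apoptosis regulators (-0.07 and 0.03), and B cell (0.08 and -0.08), plasma cell (0.03 and -0.12) and CD8 T and NK markers (0.06 and -0.23), none past the threshold as a set. Ighm, a B cell transcript, stood between 11.9 and 12.7 on all 12 arrays.

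Sex-linked genes separated the arrays by replicate number. Xist, expressed from the inactive X chromosome, was 5.55 to 6.09 on the 4 arrays numbered 2 and 12.2 to 12.6 on the other 8, while the Y-linked gene Uty was 10.01 to 10.65 and 4.03 to 4.45. Kdm5d and Eif2s3y followed Uty. The number is balanced over the groups, and the sex-linked list was not past the threshold in any comparison (camera adjusted p 0.946 to 0.983). With a sex term, 1059 genes were called in KO against WT TFH cells and 21 in KO against WT Th1 cells.

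A hypothesis was that genes next to Tcf7, carried along with the targeted allele from another strain, make up part of the calls in KO TFH cells. Of the 200 genes nearest to Tcf7, 6 were called in KO TFH cells, where 9.50 would be by chance (one-sided Fisher's exact test, p = 0.918), and 0 in Th1 cells, where 12 of all genes were called. The test gives no excess near Tcf7, which argues against such genes as a source of many calls.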
